A study of Homo sapiens with 8 samples.

How the data were processed

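The deposited gene tables were used as given by the authors, with 1 value per gene and library. The values were treated as FPKM, scaled before deposition by the authors to gene length in kilobases and to 1 factor per library. The unit was not stated with the deposited values, and it was read from the values themselves. Every value multiplied by the listed gene length was a whole multiple of 1 step per library, within 0.01 of a whole number for at least 99.9892% of values. Dividing by that step gave the number of reads behind each value. The library total implied by the step was not the total of the listed genes, and the scaling factor was not stated. Recovered reads were 2.22 and 2.17 times the implied total in Hep3B and 1.45 and 1.43 times in SK-Hep1. They were 0.527 and 0.529 times in Xeno-Hep3B and 0.58 times in both Xeno-SK-Hep1 libraries. In the parental libraries recovered reads exceeded the implied total, so that total was not a plain count of reads. The ratio separated parental from xenograft libraries, so FPKM levels of the compared groups rest on an unknown factor. Whether it held a normalization between libraries was not stated, and scaling to total reads would undo one.

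The submitters reported RNA extraction with TRIzol, libraries from 1 ug of total RNA with a TruSeq RNA kit, and alignment with Bowtie2 2.0.6 and TopHat2 2.0.9 to hg19. The coordinates in the tables were those of GRCh38: of 58302 genes, 58039 were found in GENCODE release 29, and 97.528% of these had the same coordinates. All coordinates given here are on build GRCh38. GC content came from GENCODE transcripts and was available for 99.448% of genes. The tables held 19847 protein-coding genes, and 27 gene names had been turned into dates by spreadsheet software; such genes kept their Ensembl identifiers. The kit does not mark the strand, so values of antisense and overlapping genes are uncertain, as are those of pseudogenes and close paralogs.

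Depth was taken from the recovered reads, 19.7 to 37.4 M per library. A floor of 3 reads over a group was used for bounds on folds where a group read 0, and it corresponded to 0.0216 to 0.12985 FPKM per group for a gene of 1 kb. Floors and bounds cover counting error only. The median SD between replicates on the log2 scale was 0.0288 to 0.0503 per group.

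Genes with at least 1 FPKM in at least 2 libraries were tested. Values were transformed as log2 of FPKM plus 1, and a linear model with 4 group means was fitted in limma 3.58.1 (R 4.3.3) with an intensity trend in the variance prior, on 4 residual degrees of freedom. The contrasts were Xeno-Hep3B against Hep3B, Xeno-SK-Hep1 against SK-Hep1, the difference of these changes (SK-Hep1 minus Hep3B), and SK-Hep1 against Hep3B. P-values were adjusted by the Benjamini-Hochberg method within each contrast, a gene was called at an adjusted p of 0.05, and all adjusted p-values given here come from limma. Of 37 fixed gene lists, 28 held pathways, families and RNA classes and 9 held markers of other cell types. Lists with at least 3 tested members were tested with camera in limma against all other genes at a preset inter-gene correlation of 0.01, and also with a correlation estimated from the data. With so few libraries the estimated correlation gave little power. It called no list between the parental lines, where hepatocyte genes were lower in 23 of 23 (camera adjusted p = 0.0675). A missing call with it therefore decides little. The lists called unadjusted in the xenograft comparisons lay further from a call with it (camera adjusted p = 0.759 in Hep3B and 0.839 in SK-Hep1). The preset correlation is an assumption that was not tested, so list calls depend on it.

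Groups, contrasts, filters, lists, the rule for naming genes and the alternatives of the next sentence were chosen before the data were examined. Those alternatives were a pseudocount of 0.1, quantile normalization, no low-value filter, a filter of 5 FPKM, limma without the trend, only the libraries compared, a replicate block, each library left out, an absolute log2 fold change of at least 1, and the estimated correlation. Named coding genes had to pass the test, reach a mean of 5 FPKM in a group and show no overlap between the libraries of the groups (noncoding RNAs: 1 FPKM). The 8 largest rises and falls were named per xenograft contrast for coding genes and the 3 largest for noncoding RNAs. Further named genes were 3 members of the 5 lists with the smallest adjusted p per contrast, 2 members per marker list, 5 genes per direction for both lines and for the difference between the lines, and 3 per direction plus 7 fixed genes for the parental lines. Small RNA and immunoglobulin or T cell receptor genes were not named.

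The remaining settings were chosen after the data had been seen, because the changes followed GC content. In form 1 of a GC and length adjustment, each library's trend of log2 values, taken as deviations from the gene's mean, was fitted on GC content of the longest transcript (natural spline, 6 degrees of freedom) and log2 gene length (4 degrees of freedom) and subtracted. In form 2 the GC trend could also depend on the mean level (3 degrees of freedom) and libraries were centred on their medians. Form 3 was form 2 with GC content as the median over the gene's basic transcripts. Each form was chosen after the calls of the earlier ones had been seen, and none was preferred. Also added were scaling to the total of listed reads, voom on recovered reads with the implied totals, the 3 forms with an absolute log2 change of at least 1. Fits were also restricted to genes expressed in the libraries compared, meaning a mean of at least 1 FPKM in a group of the contrast (in each line for the difference between lines). Except for the difference between lines, these restricted fits also left out the libraries of the groups not compared. They thus had fewer residual degrees of freedom. The restricted fits were added because the 3 forms gave changes to genes absent from a line: ALB in SK-Hep1, at 0 and 0.00412 FPKM, had log2 changes of -1.06, -0.79 and -0.93 in the 3 forms against 0.01 unadjusted.

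The procedure was tested on simulated data with 12746 genes of which 200 were changed. Without a GC trend, 62.32%, 92.06% and 98.53% of genes changed by 0.5, 1 and 2 log2 units were recovered and 0.088% of unchanged genes were called. With a GC trend made on the longest transcript, 78.981% of unchanged genes were called without adjustment and 31.946%, 0.151% and 18.556% with forms 1, 2 and 3; with a trend made on basic transcripts these were 77.65%, 47.362%, 16.316% and 0.096%. Beyond a 2-fold change the adjusted fits called at most 0.311% of unchanged genes and the unadjusted fit up to 7.484%. The simulated trend was linear in GC content and was made equal at every level and in both lines. The real trend differed between the lines, and the real unadjusted fit called 7015 of 12765 genes past a 2-fold change in Hep3B. The simulated rates therefore do not carry over to the data. Of 20 simulated lists, camera called the 1 raised list and 0 others. Relations across genes are given as correlation coefficients with genes as units, and genes are not independent replicates. Bootstrap intervals used 10000 draws over list members, and permutation tests used 100000 permutations. Reads of mouse origin could not be assessed from these tables and were not analysed here. Values of some genes are not reported here.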

Results

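Cells of the liver cancer lines Hep3B and SK-Hep1 were compared with xenografts of the same lines grown in nude mice, in a study looking for noncoding RNAs involved in liver cancer metastasis. Hep3B is a hepatocellular carcinoma line with hepatocyte features; SK-Hep1 is a line from a liver adenocarcinoma that has been described as endothelial in type. The 4 groups (Hep3B, Xeno-Hep3B, SK-Hep1, Xeno-SK-Hep1) had 2 libraries each. Reads recovered from the values were 19.7 and 30.8 M in Hep3B, 35.9 and 37.4 M in Xeno-Hep3B, 20.3 and 20.6 M in SK-Hep1, and 20.9 and 27.9 M in Xeno-SK-Hep1. Values are means in FPKM ± SD with n = 2 libraries per group, changes are xenograft minus parental on the log2 scale of FPKM plus 1, and floors and bounds on folds cover counting error only. The unknown scaling of the FPKM values differed between parental and xenograft libraries. The labels did not say whether replicates were separate cultures or animals, so the spread between them may be technical only. They also did not say whether the xenograft libraries came from tumour tissue or from cells cultured again after grafting.

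The first question was which genes differ between Xeno-Hep3B and Hep3B cells. ALB, the gene of serum albumin, rose from 155 FPKM ± 5.9 (SD, n = 2) to 1378 FPKM ± 66.4 (SD, n = 2). The fetal liver gene AFP rose from 1.9 FPKM ± 0.00207 (SD, n = 2) to 20.6 FPKM ± 0.552 (SD, n = 2). KLF2, a transcription factor of quiescent cells, fell from 169.8 FPKM ± 14.2 (SD, n = 2) to 2.62 FPKM ± 0.802 (SD, n = 2). The stress cytokine gene GDF15 fell from 4237 FPKM ± 130.4 (SD, n = 2) to 116 FPKM ± 5.06 (SD, n = 2). Of 12765 genes tested, 5234 were higher and 6076 lower in the xenograft libraries. The changes ran with the GC content of the transcripts. Genes and groups are therefore also given after adjustment for GC content and gene length in 3 forms, all chosen after the data had been seen. These 4 genes kept their direction and their call in all 3.

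The 8 largest falls among coding genes were KLF2, DOK7, PHLDA2, CTU1, OSGIN1, GDF15, IER5L and MAZ, with log2 changes from -5.58 ± 0.14 (SE) to -5.09 ± 0.13 and adjusted p-values from 1.01e-08 for KLF2 to 1.24e-08 for MAZ. All 8 stayed lower in the 3 adjusted forms, where KLF2 changed by -3.58, -2.07 and -1.85 and MAZ by -3.10, -1.49 and -1.64. Besides KLF2 (ENSG00000127528, chr19:16324817-16327874) and GDF15 (ENSG00000130513, chr19:18374731-18389176) these were DOK7 (ENSG00000175920, chr4:3463311-3494483), an adaptor of the muscle receptor kinase, 110.3 ± 7.57 to 1.56 ± 0.101 FPKM (n = 2 per group). PHLDA2 (ENSG00000181649, chr11:2928273-2929455), an imprinted growth repressor, fell from 1697 ± 70.9 to 38.9 ± 4.65 FPKM. CTU1 (ENSG00000142544, chr19:51097606-51108370), a tRNA thiolation enzyme, fell from 348 ± 25.9 to 7.21 ± 0.566 FPKM. OSGIN1 (ENSG00000140961, chr16:83948282-83966332), induced by oxidative stress, fell from 76.7 ± 2.59 to 1.12 ± 0.0715 FPKM. IER5L (ENSG00000188483, chr9:129175552-129178262) fell from 1313 ± 114 to 37.3 ± 3.49 FPKM, and the zinc finger transcription factor MAZ (ENSG00000103495, chr16:29806106-29811164) from 1099.6 ± 151 to 31.4 ± 5.85 FPKM.

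The 8 largest rises were TOP2A, ALB, HSP90B1, HSP90AA1, ANP32E, AFP, ZKSCAN1 and TOP2B, with log2 changes from 3.20 ± 0.08 (SE, adjusted p = 8.39e-09) for TOP2A to 2.82 ± 0.05 (adjusted p = 1.22e-09) for TOP2B. All 8 stayed higher in the 3 adjusted forms: ALB by 1.80, 2.23 and 2.05, TOP2A by 1.63, 1.76 and 1.55, HSP90B1 by 1.68, 2.18 and 1.97. The topoisomerase of dividing cells, TOP2A (ENSG00000131747, chr17:40388516-40417950), went from 2.6 ± 0.172 to 32.1 ± 0.487 FPKM, and its paralog TOP2B (ENSG00000077097, chr3:25597905-25664907) from 1.53 ± 0.0000189 to 16.8 ± 0.659 FPKM. The chaperones of the endoplasmic reticulum and the cytosol, HSP90B1 (ENSG00000166598, chr12:103930107-103953645) and HSP90AA1 (ENSG00000080824, chr14:102080738-102139699), went from 9.1 ± 0.573 to 85.1 ± 2.63 and from 8.46 ± 0.142 to 71.3 ± 3.53 FPKM. Besides ALB (ENSG00000163631, chr4:73397114-73421412) and AFP (ENSG00000081051, chr4:73431138-73456174) the remaining genes were the histone H2A.Z chaperone ANP32E (ENSG00000143401, chr1:150218417-150236156), 1.6 ± 0.107 to 18.5 ± 0.652 FPKM, and the zinc finger gene ZKSCAN1 (ENSG00000106261, chr7:100015572-100041689), 1.43 ± 0.0216 to 16.7 ± 0.0419 FPKM.

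**Figure D1:**
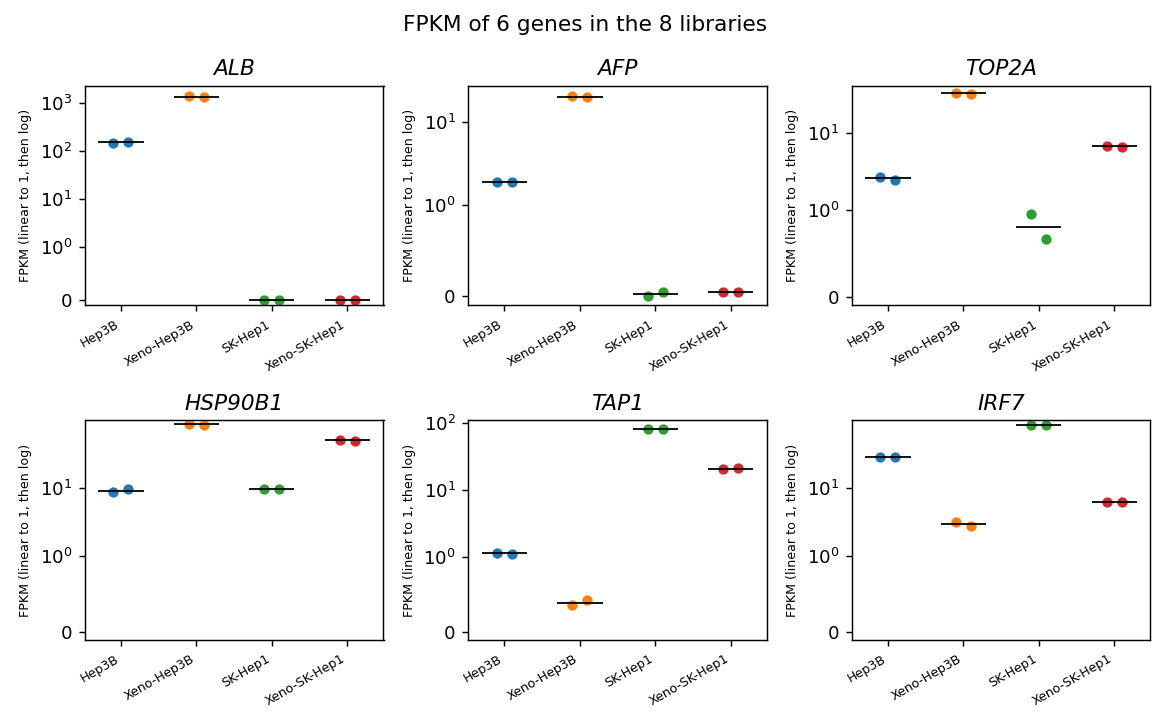
FPKM of 6 genes in the 8 libraries, on an axis that is linear to 1 and logarithmic above, with points for libraries and bars for group means. ALB rose from 155 ± 5.9 to 1378 ± 66.4 FPKM in the Hep3B line and IRF7 fell from 82.4 ± 0.0228 to 6.18 ± 0.00969 FPKM in the SK-Hep1 line.

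Hepatocyte genes of the Hep3B line moved in both directions: of 23 members tested, 9 were higher, 14 lower and 0 not called (the same counts adjusted over the list alone; adjusted p of the list = 0.597). The members named next were chosen after their values were seen, and FGG, APOH and APOB rose in all 3 adjusted forms. The fibrinogen gamma gene FGG (ENSG00000171557, chr4:154604134-154612967) went from 1.11 ± 0.25 to 9.19 ± 0.473 FPKM. The apolipoprotein genes APOH (ENSG00000091583, chr17:66212033-66256525) and APOB (ENSG00000084674, chr2:21001429-21044073) went from 17.3 ± 0.422 to 74.2 ± 2.24 and from 22.005 ± 0.763 to 84.2 ± 4.09 FPKM. The hepatocyte transcription factor gene CEBPA (ENSG00000245848, chr19:33299934-33302564), 2239 ± 175 to 109 ± 15.1 FPKM, and the transthyretin gene TTR (ENSG00000118271, chr18:31591726-31599021), 69.5 ± 3.71 to 23.7 ± 0.0559 FPKM, fell in all 3. With libraries scaled to total reads TTR was higher, by 0.49 on the log2 scale (adjusted p = 4.04e-05). The list's mean relative to all genes was -0.24 on the log2 scale unadjusted. With genes expressed in the libraries compared, it was -0.16 unadjusted and 0.02, 0.67 and 0.63 in the adjusted forms (adjusted p = 0.997, 0.0096 and 0.0299), so its size and its call depended on the form. These tests were called in none of the forms with an estimated correlation (adjusted p = 0.997, 0.503 and 0.558 with an estimated correlation).

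Apart from the markers of other cell types, 28 lists were tested in the Hep3B line and 3 were called. Glycolysis had 1 member higher, 16 lower and 2 not called (the same adjusted over the list alone), with a mean of -1.36 relative to all genes and an adjusted p of 0.00878 (adjusted p = 0.759 with an estimated correlation). Immediate early genes, which respond to growth factors within minutes, had 1 higher and 16 lower of 17 (mean -1.67, adjusted p = 0.00878). The mRNAs encoded in mitochondria had 0 higher and 13 lower of 13 (mean -0.84, adjusted p = 0.0139). Both of these also had an adjusted p of 0.759 with an estimated correlation, and the mitochondrial list's mean turned to 1.27 under quantile normalization and to 0.30 in form 2. None of the 3 calls held in all adjusted forms. Glycolysis members named by rule were ALDOA (ENSG00000149925, chr16:30053090-30070457), TPI1 (ENSG00000111669, chr12:6867119-6870948) and GAPDH (ENSG00000111640, chr12:6533927-6538374). They went from 1804 ± 22.5 to 101 ± 3.29, 606 ± 6.95 to 65.8 ± 0.0642 and 2552 ± 39.8 to 252 ± 0.553 FPKM. For immediate early genes they were IER3 (ENSG00000137331, chr6:30743199-30744554), DUSP1 (ENSG00000120129, chr5:172768090-172771195) and NR4A1 (ENSG00000123358, chr12:52022832-52059507). These went from 1849 ± 56.6 to 147 ± 5.09, 61.7 ± 2.25 to 5.79 ± 0.122 and 63.7 ± 1.12 to 3.92 ± 0.106 FPKM. These 6 genes stayed lower in all 3 forms. The mitochondrial members were MT-ND1 (ENSG00000198888, chrMT:3307-4262), MT-ND3 (ENSG00000198840, chrMT:10059-10404) and MT-CYB (ENSG00000198727, chrMT:14747-15887), at 1169 ± 53.8 to 261 ± 3.01, 2905 ± 116 to 837 ± 12.2 and 1366 ± 65.1 to 487 ± 7.69 FPKM. Only MT-ND1 stayed lower in all forms. Scaled to total reads MT-ND3 and MT-CYB were higher, by 0.26 and 0.57 on the log2 scale. The share of reads on all mitochondrial genes was 1.433% and 1.554% in Hep3B and 3.114% and 2.995% in Xeno-Hep3B. It was thus higher in the xenograft libraries, so the count of lower mitochondrial mRNAs depended on the scaling.

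Other groups of the Hep3B line were not called as lists unadjusted, though most of their genes changed. Cytosolic ribosomal proteins had 8 higher, 21 lower and 1 not called (adjusted p = 0.0891). The members RPS2 (ENSG00000140988, chr16:1962052-1964860) and RPS9 (ENSG00000170889, chr19:54200742-54249003) fell, also in all 3 forms. They went from 3149 ± 2.58 to 216 ± 1.76 and 1213 ± 14.9 to 99.7 ± 1.33 FPKM. Endoplasmic reticulum stress genes had 11 higher and 5 lower of 16 (mean 1.08, adjusted p = 0.281). In the forms their mean was 0.59, 0.94 and 0.94 (adjusted p = 0.051, 0.0109 and 0.00158; adjusted p = 0.566, 0.260 and 0.327 with an estimated correlation). With expressed genes only it was 0.60, 0.92 and 0.93 (adjusted p = 0.065, 0.0128 and 0.00138; adjusted p = 0.767, 0.503 and 0.558 with an estimated correlation). HSP90B1, SEL1L (ENSG00000071537, chr14:81471549-81533861), 1.22 ± 0.0892 to 9.36 ± 0.239 FPKM, and the gene of the chaperone BiP, HSPA5 (ENSG00000044574, chr9:125234853-125241330), 44.9 ± 2.59 to 148 ± 1.35 FPKM, were higher in all 3 forms. Heat shock genes had 6 higher and 5 lower of 11, and in the forms a mean of 0.63, 1.11 and 0.83 (adjusted p = 0.109, 0.00901 and 0.0108; adjusted p = 0.566, 0.260 and 0.327 with an estimated correlation). The ATF4 list of amino acid response genes had 6 higher and 13 lower of 19 (adjusted p = 0.281). Its members TRIB3 (ENSG00000101255, chr20:362835-397559), 1149.7 ± 33.3 to 40.3 ± 1.49 FPKM, SLC3A2 (ENSG00000168003, chr11:62856102-62888875), 368 ± 0.628 to 20.54 ± 0.173 FPKM, and SLC7A5 (ENSG00000103257, chr16:87830023-87869488), 546 ± 14.6 to 33.5 ± 0.88 FPKM, chosen after their values were seen, fell in all 3 forms. Matrix proteases and inhibitors had 1 higher, 8 lower and 4 not called, and MHC class I genes 1 higher, 8 lower and 3 not called. Relative to all genes, the means of both lists turned positive in all 3 forms. With expressed genes only, MHC class I stayed positive (0.34, 0.44 and 0.43), but the matrix proteases were negative (-0.29, -0.02 and -0.22).

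The study's own question concerned noncoding RNAs. In the Hep3B line 112 of 846 tested noncoding RNAs were higher and 497 lower (108 and 492 adjusted over the noncoding RNAs alone). Of these, 27 and 287 passed a 2-fold change (78 and 439 with a pseudocount of 0.1, 84 and 569 with voom). The balance depended on scaling and on the filter: 501 were higher and 151 lower when libraries were scaled to total reads, and 1272 higher and 813 lower of 7852 without a low-value filter. The adjusted forms gave 283, 215 and 237 higher and 417, 413 and 392 lower. The largest falls were AC068580.1 (ENSG00000229512, chr11:1763009-1763749), inside CTSD, 73.4 ± 11.7 to 2.68 ± 0.17 FPKM, and AL139246.5 (ENSG00000272449, chr1:2546465-2547460), 35.8 ± 1.81 to 1.34 ± 0.199 FPKM. They were followed by SNHG7 (ENSG00000233016, chr9:136721366-136728184), a small nucleolar RNA host gene overlapping FAM69B, 61.8 ± 1.32 to 3.72 ± 0.0163 FPKM. The largest rises were AC099850.3 (ENSG00000265415, chr17:59202677-59203829), overlapping PRR11, 1.01 ± 0.435 to 8.77 ± 1.51 FPKM, and NORAD (ENSG00000260032, chr20:36045622-36050960), which binds PUMILIO proteins, 2.83 ± 0.323 to 16.7 ± 0.181 FPKM. TUG1 (ENSG00000253352, chr22:30970677-30979395) rose from 0.974 ± 0.161 to 7.34 ± 0.506 FPKM. All 6 kept their direction in the 3 adjusted forms, NORAD with 0.80, 1.03 and 0.78. With the strand unknown, AC068580.1, SNHG7 and AC099850.3 cannot be separated from their neighbours.

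The same question was asked for SK-Hep1, where the leading genes overlapped in part with those of Hep3B. KLF2 was among the largest falls in both lines. IRF7, a regulator of the interferon response, fell from 82.4 FPKM ± 0.0228 (SD, n = 2) to 6.18 FPKM ± 0.00969 (SD, n = 2). HELZ2, an interferon-induced helicase, fell from 83.1 FPKM ± 1.51 (SD, n = 2) to 6.84 FPKM ± 0.131 (SD, n = 2). EIF3A, a translation initiation factor, rose from 4.82 FPKM ± 0.0499 (SD, n = 2) to 38.2 FPKM ± 0.535 (SD, n = 2). The adhesion molecule ALCAM rose from 4.95 FPKM ± 0.0665 (SD, n = 2) to 31.6 FPKM ± 0.012 (SD, n = 2). Of 12765 genes, 4887 were higher and 5985 lower.

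The 8 largest falls had log2 changes from -3.66 ± 0.10 (SE, adjusted p = 2.62e-08) for SEMA6B to -3.29 ± 0.08 (adjusted p = 1.59e-08) for ZNF703. All stayed lower in the 3 adjusted forms: IRF7 by -2.16, -1.48 and -1.43, SEMA6B by -2.23, -1.09 and -1.23. Besides IRF7 (ENSG00000185507, chr11:612553-615999) and HELZ2 (ENSG00000130589, chr20:63558086-63574239) they were the semaphorin gene SEMA6B (ENSG00000167680, chr19:4542593-4559808), 483 ± 5.63 to 37.4 ± 2.13 FPKM, and LRRC73 (ENSG00000204052, chr6:43506969-43510686), 50.3 ± 0.523 to 3.34 ± 0.158 FPKM. The small GTPase gene RRAD (ENSG00000166592, chr16:66921679-66925644) fell from 374 ± 0.618 to 31.5 ± 0.113 FPKM, and PRR7 (ENSG00000131188, chr5:177446445-177456286) from 344 ± 6.52 to 29.6 ± 0.674 FPKM. KLF2 fell from 326 ± 7.86 to 31.5 ± 1.23 FPKM, and ZNF703 (ENSG00000183779, chr8:37695751-37700021) from 133 ± 3.24 to 12.7 ± 0.00987 FPKM. The 8 largest rises ran from 2.75 ± 0.04 (adjusted p = 2.28e-09) for EIF3A to 2.35 ± 0.05 (adjusted p = 9.47e-09) for TNPO1. They also held in all forms, EIF3A with 1.78, 1.96 and 1.96. Besides EIF3A (ENSG00000107581, chr10:119033670-119080823) and ALCAM (ENSG00000170017, chr3:105366909-105576900) they were the kinase gene NEK7 (ENSG00000151414, chr1:198156963-198322420), 1.62 ± 0.105 to 13.2 ± 0.501 FPKM, and ERBIN (ENSG00000112851, chr5:65926475-66082549), 3.2 ± 0.113 to 20.8 ± 0.449 FPKM. The chromatin protein genes HMGB2 (ENSG00000164104, chr4:173331695-173335125) and DEK (ENSG00000124795, chr6:18223868-18264823) went from 2.21 ± 0.439 to 15.9 ± 0.604 and from 1.54 ± 0.396 to 12.1 ± 0.247 FPKM. The last were the nuclear importins IPO7 (ENSG00000205339, chr11:9384622-9448126), 2.91 ± 0.0786 to 19.3 ± 0.166 FPKM, and TNPO1 (ENSG00000083312, chr5:72816312-72916733), 2.5 ± 0.0296 to 16.8 ± 0.228 FPKM.

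Of the tested genes of antigen presentation and of the interferon response, most were lower in the SK-Hep1 xenografts. MHC class I presentation had 1 member higher and 11 lower of 12 (the same adjusted over the list alone), with a mean of -1.07 relative to all genes and an adjusted p of 0.0226 (adjusted p = 0.839 with an estimated correlation). Its named members were HLA-E (ENSG00000204592, chr6:30489467-30494205), 622 ± 11.6 to 179.9 ± 0.438 FPKM, HLA-C (ENSG00000204525, chr6:31268749-31272130), 212 ± 3.97 to 60.8 ± 0.444 FPKM, and the peptide transporter TAP1 (ENSG00000168394, chr6:32845209-32853978), 79.8 ± 0.118 to 20.8 ± 0.598 FPKM. HLA-E and TAP1 stayed lower in all 3 forms, while HLA-C was higher in forms 2 and 3. The class I list kept its negative mean in the forms (-0.56, -0.42 and -0.33), but its call in form 1 only. With expressed genes only, in fits that also left out the libraries of the Hep3B line, it was called neither unadjusted (adjusted p = 0.07435) nor in form 1 (adjusted p = 0.0646). The interferon response list had 6 higher and 11 lower of 17 and was not called unadjusted (mean -0.74, adjusted p = 0.492). In the 3 adjusted forms its mean was -0.85, -0.81 and -0.79, with adjusted p = 0.0329, 0.0030 and 0.0072 (0.684, 0.282 and 0.424 with an estimated correlation). With expressed genes only, the forms gave -0.80, -0.77 and -0.75 (adjusted p = 0.0393, 0.0034 and 0.0018; 0.91, 0.60 and 0.52 with an estimated correlation). The list of NF-kB targets and inflammatory cytokines behaved alike: 4 were higher, 12 lower and 2 not called, without a call as a list (mean -0.33, adjusted p = 0.482). In the forms its mean was -0.64, -0.55 and -0.60 (adjusted p = 0.0199, 0.00304 and 0.00208; 0.684, 0.399 and 0.424 with an estimated correlation). In Hep3B this list was also called only in the forms, at -0.64, -0.49 and -0.54 (adjusted p = 0.0394, 0.0206 and 0.0108; adjusted p = 0.566, 0.489 and 0.432 with an estimated correlation), and not with expressed genes only (adjusted p = 0.156, 0.134 and 0.0975).

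Interferon response genes that fell in every form, chosen after their values were seen, included IFI6 (ENSG00000126709, chr1:27666061-27672218), 215 ± 0.21 to 28.7 ± 0.956 FPKM, and ISG15 (ENSG00000187608, chr1:1001138-1014541), 114 ± 0.55 to 11.4 ± 0.274 FPKM. The OAS family genes OAS1 (ENSG00000089127, chr12:112906777-112933222) and OASL (ENSG00000135114, chr12:121019111-121039242) went from 9.53 ± 0.816 to 2.45 ± 0.217 and from 7.78 ± 0.171 to 0.705 ± 0.0424 FPKM. IFIT2 (ENSG00000119922, chr10:89283694-89309276), 2.47 ± 0.266 to 6.45 ± 0.239 FPKM, was higher unadjusted. The genes of MHC class II named next, in no list and also chosen after their values were seen, fell in every form and with expressed genes only. Class II genes were not counted or tested as a group. The class II regulator CIITA (ENSG00000179583, chr16:10866222-10932281) went from 15.9 ± 0.622 to 3.31 ± 0.157 FPKM. The class II genes HLA-DRB1 (ENSG00000196126, chr6:32578769-32589848), HLA-DMA (ENSG00000204257, chr6:32948613-32969094) and HLA-DPB1 (ENSG00000223865, chr6:33075926-33087201) went from 98.4 ± 3.77 to 21.03 ± 1.26, 79.1 ± 2.26 to 18.8 ± 0.107 and 35.6 ± 0.798 to 11.4 ± 0.193 FPKM. Alleles of the HLA genes vary between people and resemble one another, which makes their values less certain than those of CIITA. The chemokine gene CCL5 (ENSG00000271503, chr17:35871491-35880793), 10.9 ± 0.351 to 1.79 ± 0.0402 FPKM, and the receptor gene CD40 (ENSG00000101017, chr20:46118272-46129863), 17.7 ± 0.752 to 7.53 ± 0.199 FPKM, fell likewise. CD40 was not called when scaled to total reads (0.07 on the log2 scale, adjusted p = 0.147).

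In SK-Hep1, 4 further lists were called unadjusted. Glycolysis had 1 higher, 16 lower and 2 not called (1 and 17 adjusted over the list alone, mean -1.01, adjusted p = 0.0064). Mitochondrial mRNAs had 0 higher and 13 lower (mean -0.59, adjusted p = 0.019). Matrix proteases and inhibitors had 1 higher, 11 lower and 1 not called (mean -0.96, adjusted p = 0.0402), and immediate early genes 2 higher, 13 lower and 2 not called (mean -0.78, adjusted p = 0.0402). Each had an adjusted p of 0.839 with an estimated correlation, and none held in all adjusted forms. The mean of immediate early genes turned positive in forms 2 and 3, and that of mitochondrial mRNAs turned to 0.66 under quantile normalization. Named members were ALDOA, 969.8 ± 3.31 to 167 ± 1.07 FPKM, PKM (ENSG00000067225, chr15:72199029-72231822), 603 ± 13.9 to 157 ± 0.628 FPKM, and PFKL (ENSG00000141959, chr21:44300051-44327376), 99.4 ± 0.328 to 19.3 ± 0.207 FPKM. The mitochondrial members were MT-ND1, 708 ± 2.1 to 292 ± 6.31 FPKM, MT-ND3, 3021 ± 5.58 to 1323 ± 47.2 FPKM, and MT-CO2 (ENSG00000198712, chrMT:7586-8269), 5544 ± 160.0 to 2664 ± 63.9 FPKM. In the protease list they were the protease inhibitor TIMP1 (ENSG00000102265, chrX:47582313-47586789), 620.1 ± 2.76 to 110.4 ± 1.68 FPKM, MMP14 (ENSG00000157227, chr14:22836557-22849027), 312 ± 0.545 to 75.2 ± 1.4 FPKM, and CTSB (ENSG00000164733, chr8:11842524-11869448), 740.4 ± 5.36 to 278 ± 1.33 FPKM. Immediate early members were JUNB (ENSG00000171223, chr19:12791496-12793315), 155 ± 2.58 to 27.2 ± 0.473 FPKM, IER3, 482 ± 3.52 to 121 ± 0.156 FPKM, and FOSL1 (ENSG00000175592, chr11:65892049-65900573), 1064 ± 23.03 to 224 ± 2.24 FPKM. Of these ALDOA, PKM, MT-ND1, TIMP1 and FOSL1 stayed lower in all 3 forms. Scaled to total reads MT-ND1 was not called (0.037 on the log2 scale, adjusted p = 0.448), and MT-ND3 and MT-CO2 were higher, by 0.12 and 0.26. The share of reads on all mitochondrial genes was 1.901% and 1.845% in SK-Hep1 and 2.643% and 2.604% in Xeno-SK-Hep1. Here too the count of lower mitochondrial mRNAs depended on the scaling.

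In the SK-Hep1 line 139 of 846 noncoding RNAs were higher and 383 lower (128 and 366 adjusted over the noncoding RNAs alone). This compares with 507 and 85 when scaled to total reads, with 740 and 502 of 7852 without a low-value filter, and with 301, 225 and 233 higher with 321, 258 and 239 lower in the adjusted forms. The largest falls were MAFG-AS1 (ENSG00000265688, chr17:81927829-81930753), 49.1 ± 0.123 to 8.72 ± 0.508 FPKM, and AC233992.3 (ENSG00000272115, chr8:144409492-144409976), overlapping SLC39A4, 12.98 ± 0.867 to 1.81 ± 0.194 FPKM. AL391121.1 (ENSG00000272933, chr10:102642792-102644140), 167 ± 3.78 to 33.2 ± 2.19 FPKM, was no longer called in forms 2 and 3. The largest rises were LINC01293 (ENSG00000230836, chr2:74940258-74942670), 3.43 ± 0.659 to 18.02 ± 0.299 FPKM, NORAD, 5.0 ± 0.12 to 23.01 ± 0.436 FPKM, and AC099850.3, 1.31 ± 0.594 to 7.45 ± 1.22 FPKM, which held in all forms. LINC01293 was near 0 in the Hep3B line (0 ± 0 and 0.0172 ± 0.00851 FPKM). Over both lines 63 noncoding RNAs were higher in each and 288 lower in each, with 18.4 and 225 anticipated for independent lines, and 12 and 58 of them kept this in all 3 forms.

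Which changes were shared by the lines was the next question. DEK went from 3.12 ± 0.332 to 25.5 ± 0.885 FPKM in the Hep3B line and from 1.54 ± 0.396 to 12.1 ± 0.247 FPKM in the SK-Hep1 line. HMGB2 went from 3.09 ± 0.0751 to 21.7 ± 0.275 and from 2.21 ± 0.439 to 15.9 ± 0.604 FPKM. KLF2 and SEMA6B fell in both lines, SEMA6B from 2884 ± 296 to 128 ± 16.9 FPKM in Hep3B. Of 12765 genes 4402 were higher in both lines and 5164 lower in both, where 2003.8 and 2848.8 would be anticipated for independent lines, and 246 changed in opposite directions. The changes had a Pearson r of 0.869 across genes, which are not independent replicates. In the adjusted forms r was 0.65, 0.464 and 0.376, and 1472, 2499 and 2543 genes changed in opposite directions. Form 1 put 1812 genes higher and 6057 lower in both lines. Form 2 gave 2661 and 2916, with 1827.8 and 2005.4 anticipated, and form 3 gave 2481 and 2796. Scaled to total reads, 7520 were higher and 2463 lower in both. Among genes expressed in both lines r was 0.94 unadjusted and 0.786, 0.779 and 0.732 adjusted. There 195 genes changed in opposite directions unadjusted and 612, 619 and 693 adjusted.

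The genes named for both lines were HMGB2, DEK, ALCAM, IPO7 and PTPN11 (ENSG00000179295, chr12:112418351-112509913), a tyrosine phosphatase overlapping RPL6, upward, and SEMA6B, PRR7, KLF2, ZNF703 and METRN (ENSG00000103260, chr16:715115-719655) downward. PTPN11 rose from 2.79 ± 0.0767 to 17.8 ± 0.39 FPKM in Hep3B and 2.36 ± 0.456 to 15.1 ± 0.181 FPKM in SK-Hep1, and METRN fell from 133 ± 4.98 to 7.17 ± 0.688 and 421 ± 2.04 to 43.1 ± 0.778 FPKM. All held in the 3 forms in both lines except ZNF703, which was not called in forms 2 and 3 in Hep3B. Leaving out small RNA and immunoglobulin or T cell receptor genes, 15 genes were higher and 41 lower beyond a 2-fold change in the unadjusted fit and every form in both lines. The 15 included HSP90AA1, HSP90B1, HMGB2 and DEK. Also among them, and chosen after its values were seen, was nucleolin, NCL (ENSG00000115053, chr2:231453531-231483641), 7.78 ± 0.509 to 32.7 ± 0.84 FPKM in Hep3B and 7.99 ± 0.593 to 40.1 ± 0.404 FPKM in SK-Hep1. So was lamin B1, LMNB1 (ENSG00000113368, chr5:126776623-126837020), 6.16 ± 0.387 to 23.7 ± 0.0987 and 1.31 ± 0.0969 to 3.75 ± 0.241 FPKM. The 41 included the lncRNA CYTOR (ENSG00000222041, chr2:87455368-87606805), 5.24 ± 0.19 to 0.804 ± 0.00767 and 28.997 ± 1.69 to 12.4 ± 0.496 FPKM, and IER5 (ENSG00000162783, chr1:181088712-181092899), 23.4 ± 1.72 to 4.72 ± 0.278 and 44.8 ± 1.31 to 14.5 ± 0.311 FPKM. CYTOR was not called in SK-Hep1 when scaled to total reads (0.08 on the log2 scale, adjusted p = 0.161).

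Genes whose change differed between the lines numbered 9482, with 5263 changes higher in SK-Hep1 and 4219 higher in Hep3B. Scaled to total reads these were 3301 and 7548. Of the 5263 and 4219, 3410 and 2633 kept their direction and call in all 3 adjusted forms. Past a 2-fold difference, 664 of 1985 and 460 of 660 were kept past it in every form. TRIB3 and SLC3A2 fell far more in Hep3B than in SK-Hep1, by 2.65 and 2.35 on the log2 scale. Their ATF4 list differed by 1.01 relative to all genes (16 members higher in SK-Hep1, 1 lower, 2 not called; adjusted p = 0.0011, 0.223 with an estimated correlation). The change of immediate early genes was also higher in SK-Hep1 (0.89; 14, 1 and 2 members; adjusted p = 0.0011, 0.299 with an estimated correlation). The NRF2 list of antioxidant genes, called in neither line unadjusted, differed in the same direction (0.70; 12, 1 and 1; adjusted p = 0.0087, 0.223 with an estimated correlation). Interferon response genes (-0.92; 3, 12 and 2; adjusted p = 0.0073, 0.223 with an estimated correlation), MHC class I genes (-0.78; 1, 9 and 2; adjusted p = 0.0087, 0.303) and endoplasmic reticulum stress genes (-0.55; 1, 11 and 4; adjusted p = 0.0087, 0.223) had the lower change in SK-Hep1. These 6 lists were called in all 3 forms, and among expressed genes all but MHC class I were called unadjusted too. Scaling mattered for some: scaled to total reads the interferon list was at -0.10 (adjusted p = 0.491), MHC class I at -0.27 (adjusted p = 0.123) and NRF2 genes lost their call (adjusted p = 0.073). MHC class I also lost its call under quantile normalization and voom (adjusted p = 0.273 and 0.398). In the Hep3B line only 6 of 17 interferon genes and 7 of 12 MHC class I genes reached a mean of 1 FPKM in a group. In SK-Hep1 all 17 and all 12 did. Genes near 0 in Hep3B had little room to fall there, so part of these differences may rest on baseline levels.

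The 10 genes named for this difference were mostly genes that 1 of the lines does not express, so they show where a gene was present at all. In Hep3B DOK7, SYT12 (ENSG00000173227, chr11:67006778-67050863), 42.02 ± 2.56 to 1.66 ± 0.0351 FPKM, and the cell cycle inhibitor CDKN2A (ENSG00000147889, chr9:21967753-21995301), 2359 ± 24.5 to 150.2 ± 4.84 FPKM, fell. So did RASL10B (ENSG00000270885, chr17:35731649-35743521), 293 ± 8.75 to 18.8 ± 0.481 FPKM, and ATOH8 (ENSG00000168874, chr2:85751344-85788066), 104 ± 3.63 to 5.21 ± 0.244 FPKM, while ALB and AFP rose. In SK-Hep1 all 7 stayed at or below 0.231 ± 0.0281 FPKM, the value of ATOH8. In SK-Hep1 FAM167B (ENSG00000183615, chr1:32247233-32248856), 23.9 ± 0.741 to 2.75 ± 0.0543 FPKM, the potassium channel gene KCNN4 (ENSG00000104783, chr19:43766533-43781257), 314 ± 3.68 to 45.6 ± 1.59 FPKM, and SHANK1 (ENSG00000161681, chr19:50661827-50719450), 48.6 ± 1.17 to 6.44 ± 0.0458 FPKM, fell.

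The parental lines differed first in hepatocyte identity. ALB read 155 FPKM ± 5.9 (SD, n = 2) in Hep3B and 0 in SK-Hep1, at least 4964-fold lower, and the apolipoprotein gene APOA2 was at least 94309-fold lower. VIM, an intermediate filament gene of mesenchymal cells, was 20.4 ± 1.13 FPKM in Hep3B and 244 ± 7.09 in SK-Hep1. Of 12765 genes 5218 were higher in SK-Hep1 and 5777 lower, and 4137 and 4902 of them kept this in all 3 adjusted forms. Scaled to total reads 7146 were higher and 4042 lower.

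The genes highest in SK-Hep1 relative to Hep3B were SLC18A3 (ENSG00000187714, chr10:49610301-49612720), 0.0232 ± 0.0329 to 1082 ± 0.441 FPKM, and the plasminogen activator PLAT (ENSG00000104368, chr8:42175233-42207724), 0.0627 ± 0.0166 to 606 ± 12.1 FPKM. The glutathione transferase GSTP1 (ENSG00000084207, chr11:67583595-67586660), 0 ± 0 to 722 ± 6.93 FPKM, was at least 10647-fold higher. Highest in Hep3B were APOA2 (ENSG00000158874, chr1:161222292-161223631), 10540.0 ± 88.5 to 0 ± 0 FPKM, AMBP (ENSG00000106927, chr9:114060127-114078472), 2553 ± 13.4 to 0 ± 0 FPKM, at least 49340.0-fold, and CDKN2A, 2359 ± 24.5 to 0 ± 0 FPKM, at least 96713-fold. Of the genes fixed beforehand, ALB, HNF4A, EPCAM, CDH1 and VIM followed the lines' types. HNF4A (ENSG00000101076, chr20:44355700-44434596), 35.2 ± 0.586 to 0.0288 ± 0.013 FPKM, EPCAM (ENSG00000119888, chr2:47345158-47387601), 15.2 ± 1.1 to 0.0413 ± 0.0585 FPKM, and CDH1 (ENSG00000039068, chr16:68737225-68835548), 4.22 ± 0.391 to 0 ± 0 FPKM, at least 247-fold, were lower in SK-Hep1. AFP was low in both lines, 1.9 ± 0.00207 FPKM in Hep3B and 0.0213 ± 0.0301 FPKM in SK-Hep1. VIM (ENSG00000026025, chr10:17228259-17237593), 20.4 ± 1.13 to 244 ± 7.09 FPKM, was higher in SK-Hep1.

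Hepatocyte genes were lower in SK-Hep1 in 23 of 23 (mean -6.00 relative to all genes, adjusted p = 5.03e-09; 0.0675 with an estimated correlation). Cell cycle genes were lower in 24 of 24 and cholesterol synthesis genes in 19 of 21. MHC class I genes were higher in SK-Hep1 in 12 of 12 and interferon response genes in 16 of 17 with 1 lower. Matrix proteases and inhibitors were higher in 12 of 13 with 1 lower, and collagens and matrix in 15 of 18 with 3 lower. Their adjusted p-values were 3.73e-05 (cell cycle, cholesterol, MHC class I), 5.21e-05 (interferon), 5.37e-05 (matrix proteases) and 0.000647 (collagens), and with an estimated correlation 0.131, 0.0759, 0.131, 0.0759, 0.0759 and 0.0937.

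Across the whole of each xenograft comparison, the direction of change followed GC content. Among 11170 coding genes the Spearman rho of change and GC content was -0.839 in Hep3B and -0.851 in SK-Hep1, across genes, which are not independent replicates. The 1117 coding genes of lowest GC content (31.12% to 40.09%) had median changes of 1.18 and 0.92, that is 2.26-fold and 1.89-fold up, and the 1117 of highest GC content (63.33% to 76.39%) had -2.86 and -2.05, that is 7.24-fold and 4.15-fold down. The mean GC content of the reads was 60.3% and 60.1% in Hep3B, 58.5% in both SK-Hep1 libraries, 52.95% and 53.2% in Xeno-Hep3B and 53.2% and 53.3% in Xeno-SK-Hep1, so GC content and group cannot be separated by sample. The genes KLF2, GDF15, IRF7 and SEMA6B are GC-rich (66.8%, 62.9%, 66.8% and 66.2%) and ALB, AFP, TOP2A and EIF3A are not (42.3%, 40.02%, 39.1% and 45.2%).

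**Figure D2:**
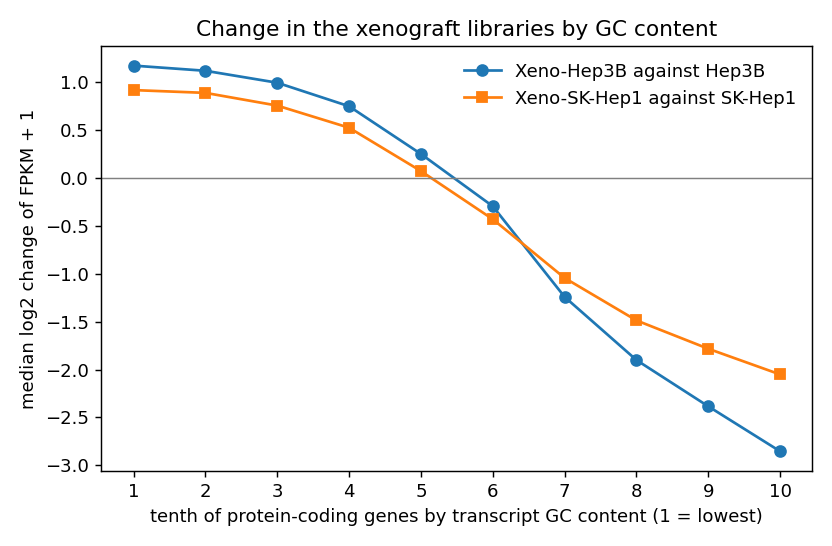
Median log2 change of FPKM plus 1 (vertical) over 10 equal groups of coding genes ordered by transcript GC content (horizontal, 1 lowest), for both xenograft comparisons. Medians went from 1.18 to -2.86 in Hep3B and from 0.92 to -2.05 in SK-Hep1.

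Of the Hep3B calls, 1583 of 5234 higher genes and 2920 of 6076 lower genes kept their direction and call in all 3 adjusted forms, and 806 and 518 were called the opposite way in all of them. In SK-Hep1 1419 of 4887 and 2799 of 5985 were kept and 693 and 396 turned. The forms left part of the GC trend among coding genes. There rho was -0.182, -0.148 and -0.0575 in Hep3B and -0.217, -0.166 and -0.078 in SK-Hep1. Among all tested genes, past a 2-fold change in the unadjusted fit and every form, there were 124 genes higher and 565 lower in Hep3B and 54 and 169 in SK-Hep1; ALB, TOP2A and HSP90B1 were among the 124, EIF3A among the 54. The split into higher and lower also depended on scaling, filter and form. Scaled to total reads, 9032 genes were higher and 3018 lower in Hep3B and 8229 and 3373 in SK-Hep1, with the median of all genes at 0.96 and 0.56 against -0.07 and -0.08 before. Form 1 gave 3196 and 7743 in Hep3B and 3071 and 7388 in SK-Hep1 (medians -0.41 and -0.31), and a filter of 5 FPKM gave 2065 and 4805, and 1956 and 4771 (medians -1.20 and -0.88). Form 2 gave 5233 higher and 5169 lower in Hep3B and 4452 and 4945 in SK-Hep1, and form 3 gave 5130 and 5102, and 4256 and 4972. Without a low-value filter 8879 were higher and 6955 lower in Hep3B and 6838 and 6536 in SK-Hep1. Medians were -0.50 and -0.43 with voom and -0.15 and -0.18 with a pseudocount of 0.1. Among expressed genes they were -0.37 and -0.32.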

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

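The tests of the relation with GC content were set before their values were seen, and the tests of the shared changes and of the interferon and MHC class I genes after the pattern had been seen. All are made on the data that showed the patterns, so what follows are hypotheses.

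In both lines the direction of change followed GC content. The genes of cytosolic ribosomal proteins, made in fixed proportions, showed the same relation (76 genes of 42.62% to 62.44% GC; Spearman rho -0.8253 in Hep3B, the weaker line, and -0.861 in SK-Hep1; permutation p = 1e-05 in each, the smallest that 100000 permutations can give). A GC-dependent library bias may therefore underlie much of the pattern, since a true response would have to order ribosomal protein genes by base composition. Gene length bias would have lost the relation within 4 classes of gene length, and the weakest rho there was -0.7703, which argues against it. Because every xenograft library had the lower GC content, a real shift of GC-rich transcripts stays open.

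The changes of the lines were correlated across genes. A shared GC and length trend may account for part of this, because the Pearson r of 0.869 fell to 0.3757 in the lowest of the 3 adjusted forms, between the bounds of 0.2 and 0.4 set for the test, which leaves it undecided. Among genes expressed in both lines the lowest r was 0.7321, which argues against the gene-level trend as the whole cause. The bound of that test was rewritten after its value was seen. The first bound asked for no GC trend in each of the 3 forms, and under it the test stays undecided, because form 1 left rho at -0.111 and -0.144 and form 2 at -0.155 and -0.157. Only form 3 (rho -0.0605 and -0.0531) met it. These rho cover all genes. Among coding genes alone they were -0.191 and -0.221 in form 1, -0.187 and -0.201 in form 2, and -0.0886 and -0.0956 in form 3. Bias that GC content and length of whole genes do not capture stays open.

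Of 17 interferon response genes 11 were lower in the SK-Hep1 xenografts, and of 12 MHC class I genes 11. The interferon list was not called unadjusted (adjusted p = 0.492) but in all 3 adjusted forms (adjusted p = 0.684, 0.282 and 0.424 with an estimated correlation). The MHC class I list was called unadjusted and in form 1 only (unadjusted fit: adjusted p = 0.0226; adjusted p = 0.839 with an estimated correlation). With expressed genes only, in fits that also left out the libraries of the Hep3B line, both of these calls were lost (adjusted p = 0.07435 and 0.0646). A shared GC and length trend does not account for the interferon response genes in these forms: their mean nearest 0 was -0.7881, with 95% bootstrap intervals over members of -1.23 to -0.48, -1.17 to -0.47 and -1.12 to -0.46. For MHC class I genes the mean nearest 0 was -0.3322, with upper bootstrap bounds of -0.29, -0.06 and -0.04 that passed the bound of -0.3 set for the test, so this list and the trend cannot be told apart. A change in cell density or culture-wide transcription may lower many response lists, but only 1 of 7 other response lists, the NF-kB list, fell by as much as MHC class I, the list nearer 0. The NF-kB means (-0.64, -0.55 and -0.60) were nearer 0 than those of the interferon list (-0.85, -0.81 and -0.79). They lay inside the bootstrap intervals of that list, so the sizes do not separate the 2 lists. In Hep3B the NF-kB list fell in the forms too (-0.64, -0.49 and -0.54). The count of 1 in 7 argues against a fall of most response lists. It cannot separate the interferon fall from a change that lowers only some of them, such as the NF-kB list. The interferon list was not called with an estimated correlation, and the state of the cultures was not recorded.

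The remaining results are differences between the lines that were tested. Genes whose change differed numbered 9482. Of 5263 changes higher in SK-Hep1 and 4219 lower there, 3410 and 2633 held in all 3 adjusted forms. The changes were higher in SK-Hep1 for DOK7 (5.41), SYT12 (4.01), CDKN2A (3.97), RASL10B (3.90) and ATOH8 (3.85), genes near 0 in SK-Hep1. They were lower in SK-Hep1 for ALB (-3.14), AFP (-2.86), FAM167B (-3.05), KCNN4 (-2.76) and SHANK1 (-2.75), each near 0 in 1 of the lines. Among lists the changes were higher in SK-Hep1 for ATF4 amino acid response (1.01), immediate early genes (0.89), cytosolic ribosomal proteins (0.73), NRF2 genes (0.70), cholesterol synthesis (0.58) and oxidative phosphorylation (0.37). They were lower in SK-Hep1 for the interferon response (-0.92), fibroblast markers (-0.83), MHC class I presentation (-0.78), collagens and matrix (-0.63) and endoplasmic reticulum stress (-0.55). Most interferon genes and some MHC class I genes stayed below 1 FPKM in the Hep3B line, which limits how far they could fall there. The differences of ribosomal proteins, cholesterol synthesis, oxidative phosphorylation, collagens and fibroblast markers were not called in all 3 adjusted forms. With an estimated correlation none of these 11 list differences was called (adjusted p from 0.223 to 0.453 with an estimated correlation). That test called no list between the parental lines either, so its missing calls decide little. Scaled to total reads, the differences of the interferon response, MHC class I, NRF2, cholesterol synthesis, oxidative phosphorylation, collagen and fibroblast lists lost their call (adjusted p = 0.491, 0.123, 0.073, 0.170, 0.406, 0.491 and 0.334).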

How the results depend on the processing

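Each library was left out in turn, and no gene count moved. The ranges (min, max) were 10949 to 11350 changed genes in Hep3B, 10467 to 11035 in SK-Hep1, 9254 to 9627 changed the same way in both lines, 8621 to 9644 with a different change between the lines and 10705 to 10873 different between the parental lines. The count of noncoding RNAs changed in Xeno-Hep3B against Hep3B ranged from 565 to 617, and that of noncoding RNAs changed in Xeno-SK-Hep1 against SK-Hep1 from 452 to 537. Called lists ranged from 3 to 3 and from 4 to 5. Limma without the trend, a pseudocount of 0.1, voom and only the libraries compared left every count of called genes within a factor of 1.5 where no fold change was required, and with voom 128 of the named genes' results stayed as they were. Turned signs are listed below for gene lists and for genes named by rule, unless stated otherwise. The cause was not tested for any of the differences that follow. With 2 libraries per group, no estimate here separates variation between animals or cultures from technical variation.

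With a replicate block, treating replicate numbers as paired, 11292 genes changed in Hep3B, 10834 in SK-Hep1, 9525 the same way in both lines, 9372 differently between the lines and 10931 between the parental lines, with 606 noncoding RNAs changed in Xeno-Hep3B against Hep3B, 521 noncoding RNAs changed in Xeno-SK-Hep1 against SK-Hep1, and 3 and 5 lists. The labels did not say that numbers pair, and the deviations of replicates correlated by only -0.0981 to 0.059 across genes between groups.

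Unadjusted, there were 11310 changed genes in Hep3B and 10872 in SK-Hep1, 9566 changed the same way in both lines. There were 9482 with a different change between the lines, 10995 different between the parental lines, 609 noncoding RNAs in Hep3B and 522 in SK-Hep1, 3 lists in Hep3B and 5 in SK-Hep1. A filter of 5 FPKM gave 6870 changed genes in Hep3B and 6727 in SK-Hep1, 6134 changed the same way in both lines. There were 6121 with a different change between the lines, 6859 different between the parental lines, 191 noncoding RNAs in Hep3B and 173 in SK-Hep1, 0 lists in Hep3B and 0 in SK-Hep1. That filter turned the sign in Hep3B of MHC class I presentation (0.23). Requiring an absolute log2 change of at least 1 left 7015 changed genes in Hep3B and 5268 in SK-Hep1, 4390 changed the same way in both lines. There were 2645 with a different change between the lines, 4911 different between the parental lines, 314 noncoding RNAs in Hep3B and 117 in SK-Hep1. Those counts rest on the pseudocount of 1. With a pseudocount of 0.1 they were 9223 genes in Hep3B and 7912 in SK-Hep1, with 78 noncoding RNAs higher and 439 lower in Hep3B and 80 and 260 in SK-Hep1. With voom they were 9926 and 8635 genes, with 84 noncoding RNAs higher and 569 lower in Hep3B and 83 and 350 in SK-Hep1. Without a low-value filter there were 2085 noncoding RNAs in Hep3B and 1242 in SK-Hep1, 9 lists in Hep3B. An estimated correlation left 0 lists in Hep3B and 0 in SK-Hep1. Quantile normalization gave 6 lists in Hep3B. It turned the sign in Hep3B of mitochondrially encoded mRNAs (1.27), MT-ND1 (0.79), MT-ND3 (0.73) and MT-CYB (1.4969). For SK-Hep1 it turned mitochondrially encoded mRNAs (0.66), MT-ND1 (0.41), MT-ND3 (0.49), MT-CO2 (0.23) and CTSB (0.24). Scaling to total reads gave 2 lists in SK-Hep1. That scaling turned the sign in Hep3B of MT-ND3 (0.26) and MT-CYB (0.57). For SK-Hep1 the values turned were MT-ND1 (0.037), MT-ND3 (0.12) and MT-CO2 (0.26). Of the genes chosen after their values were seen, TTR (0.49), MALAT1 (1.21), GAS5 (0.93), UCA1 (0.29) and PVT1 (0.0529) turned in Hep3B, and PVT1 (0.19), MALAT1 (0.14), CD40 (0.0724) and CYTOR (0.0819) in SK-Hep1.

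Form 1 of the adjustment turned the sign in Hep3B of matrix proteases and their inhibitors (0.18), MHC class I presentation (0.36), LUM (-0.11) and PDGFRA (-0.13). For SK-Hep1 this held for FCER1G (-0.42) and CORO1A (0.67). Form 2 gave 5577 changed the same way in both lines. Form 2 turned the sign in Hep3B of matrix proteases and their inhibitors (0.53), mitochondrially encoded mRNAs (0.30), MHC class I presentation (0.58), MT-ND3 (0.59), MT-CYB (0.12) and EGFL7 (0.30). For SK-Hep1 the turned values were immediate early genes (0.13), AL391121.1 (0.0402), MT-ND3 (0.39), MT-CO2 (0.24), HLA-C (0.42), FCER1G (-0.095), CORO1A (0.23), FOXJ1 (0.18) and ABCA3 (0.0122). Form 3 gave 5277 changed the same way in both lines, 3 lists in SK-Hep1. Form 3 turned the sign in Hep3B of matrix proteases and their inhibitors (0.30), MHC class I presentation (0.69), MT-ND3 (0.56), EGFL7 (0.34) and CFD (0.26). For SK-Hep1 they were immediate early genes (0.15), AL391121.1 (0.12), PFKL (0.0597), MT-ND3 (0.58), MT-CO2 (0.0614), HLA-C (0.26), CTSB (0.0407), FCER1G (-0.0484), CORO1A (0.20), FOXJ1 (0.23) and CFD (0.15). With form 1 and a log2 change of at least 1 there were 4166 changed genes in Hep3B and 2280 in SK-Hep1, 1575 changed the same way in both lines. There were 2001 with a different change between the lines, 4675 different between the parental lines, 298 noncoding RNAs in Hep3B and 152 in SK-Hep1. With form 2 and a log2 change of at least 1 there were 2149 changed genes in Hep3B and 944 in SK-Hep1, 516 changed the same way in both lines. There were 1653 with a different change between the lines, 4561 different between the parental lines, 158 noncoding RNAs in Hep3B and 53 in SK-Hep1. With form 3 and a log2 change of at least 1 there were 1793 changed genes in Hep3B and 736 in SK-Hep1, 343 changed the same way in both lines. There were 1608 with a different change between the lines, 4549 different between the parental lines, 152 noncoding RNAs in Hep3B and 49 in SK-Hep1.

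Restricting the fit to expressed genes and to the libraries compared gave 2 lists in SK-Hep1. Expressed genes in form 1 gave 6073 changed the same way in both lines, 6290 with a different change between the lines, 3 lists in SK-Hep1. There form 1 turned the sign in Hep3B of MHC class I presentation (0.34), LUM (-0.29), PDGFRA (-0.32) and CORO1A (0.0112). For SK-Hep1 it turned only immediate early genes (0.0014). Expressed genes in form 2 gave 4793 changed the same way in both lines, 5904 with a different change between the lines, 313 noncoding RNAs in SK-Hep1, 5 lists in Hep3B and 3 in SK-Hep1. This setting turned the sign in Hep3B of mitochondrially encoded mRNAs (0.22), MHC class I presentation (0.44), MT-CYB (0.0507) and EGFL7 (0.17). For SK-Hep1 these were immediate early genes (0.17), AL391121.1 (0.15), PFKL (0.0042), MT-ND3 (0.14), MT-CO2 (0.14), HLA-C (0.52), CD14 (0.11), FOXJ1 (0.097), ABCA3 (0.30) and CFD (0.0183). Expressed genes in form 3 gave 4494 changed the same way in both lines, 5790 with a different change between the lines, 314 noncoding RNAs in SK-Hep1, 5 lists in Hep3B and 3 in SK-Hep1. Form 3 among expressed genes turned the sign in Hep3B of MHC class I presentation (0.43), MT-ND3 (0.0513), EGFL7 (0.22), CFD (0.26) and ZNF703 (0.0108). For SK-Hep1 the sign turned for immediate early genes (0.17), AL391121.1 (0.25), PFKL (0.13), MT-ND3 (0.32), HLA-C (0.36), CTSB (0.13), JUNB (0.0265), IER3 (0.0434), CD14 (0.16), FOXJ1 (0.17), ABCA3 (0.23) and CFD (0.24).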

Other observations

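Genes of cell division and of cholesterol synthesis were divided within their lists in both lines. In Hep3B 16 of 24 cell cycle genes were higher and 8 lower, and in SK-Hep1 14 were higher, 9 lower and 1 not called. With expressed genes only, the adjusted forms put the Hep3B cell cycle list above all genes by 0.48, 0.68 and 0.47 on the log2 scale (adjusted p = 0.0185, 0.0026 and 0.0299; adjusted p = 0.767, 0.503 and 0.558 with an estimated correlation). For SK-Hep1 these were 0.28, 0.28 and 0.17 (adjusted p = 0.176, 0.0117 and 0.133; adjusted p = 0.907, 0.601 and 0.523 with an estimated correlation). The genes named next were chosen after their values were seen and kept their direction in all 3 adjusted forms. The proliferation marker MKI67 (ENSG00000148773, chr10:128096659-128126385) rose from 1.45 ± 0.154 to 6.77 ± 0.15 FPKM in Hep3B and 0.541 ± 0.0707 to 2.56 ± 0.0408 FPKM in SK-Hep1. Cyclin A2, CCNA2 (ENSG00000145386, chr4:121816444-121823933), 2.85 ± 0.182 to 13.3 ± 0.50 and 0.654 ± 0.0224 to 3.8 ± 0.175 FPKM, rose. The transcription factor E2F1 (ENSG00000101412, chr20:33675683-33686404), 218 ± 19.3 to 11.8 ± 1.24 and 15.5 ± 0.364 to 2.28 ± 0.0162 FPKM, fell. Of 21 cholesterol synthesis genes 7 were higher and 14 lower in each line. The early enzyme gene HMGCS1 (ENSG00000112972, chr5:43289395-43313512), 5.21 ± 0.609 to 37.4 ± 0.829 and 1.27 ± 0.00622 to 8.18 ± 0.0876 FPKM, rose in all forms. The later enzymes MVD (ENSG00000167508, chr16:88651935-88663161), 591 ± 18.5 to 37.3 ± 0.886 FPKM, and DHCR7 (ENSG00000172893, chr11:71428193-71452868), 818 ± 1.42 to 74.3 ± 0.95 FPKM, fell in all forms in Hep3B. The GC content of HMGCS1 is 40.1%, and that of MVD and DHCR7 is 65.6% and 58.1%.

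Of the lncRNAs known from liver cancer and metastasis, 24 were tested: 4 were higher, 17 lower and 3 not called in Hep3B, and 9, 10 and 5 in SK-Hep1 (adjusted p = 0.281 and 0.941). With expressed genes only, the Hep3B mean relative to all genes was -0.19 unadjusted and -0.55, -0.66 and -0.75 in the forms. The list was called in form 3 only (adjusted p = 0.563, 0.0533 and 0.0438; 0.777, 0.503 and 0.558 with an estimated correlation). In SK-Hep1 the mean was 0.30 unadjusted and 0.12 in form 1, without a call (adjusted p = 0.867 and 0.494). The members named here were chosen after their values were seen. MALAT1 (ENSG00000251562, chr11:65497762-65506516), 4.13 ± 0.532 to 2.99 ± 0.0821 FPKM in Hep3B and 5.66 ± 0.0563 to 2.57 ± 0.0443 FPKM in SK-Hep1, was lower in both lines in all forms. So were PVT1 (ENSG00000249859, chr8:127794533-128101253), 1.1 ± 0.0115 to 0.294 ± 0.000545 and 4.11 ± 0.243 to 1.97 ± 0.187 FPKM, and SNHG15 (ENSG00000232956, chr7:44983023-44986961), 15.9 ± 0.364 to 1.13 ± 0.0782 and 7.03 ± 0.159 to 2.77 ± 0.27 FPKM. MIR22HG (ENSG00000186594, chr17:1711493-1717174), 1.06 ± 0.0988 to 2.0 ± 0.0378 and 2.89 ± 0.475 to 7.66 ± 0.0462 FPKM, was higher in both. In Hep3B GAS5 (ENSG00000234741, chr1:173863900-173868882), 23.01 ± 1.23 to 11.1 ± 0.802 FPKM, UCA1 (ENSG00000214049, chr19:15828961-15836320), 11.04 ± 1.09 to 3.36 ± 0.029 FPKM, and DANCR (ENSG00000226950, chr4:52712404-52720351), 149 ± 0.65 to 19.99 ± 0.421 FPKM, were lower in all forms. Several of these falls were lost when libraries were scaled to total reads. Then MALAT1, GAS5 and UCA1 were higher in Hep3B (by 1.21, 0.93 and 0.29 on the log2 scale) and PVT1 in SK-Hep1 (by 0.19). PVT1 in Hep3B (0.05) and MALAT1 and SNHG15 in SK-Hep1 (0.14 and -0.03) were not called in that setting.

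Markers of other cell types are given as the 2 members of each list with the highest mean in the xenografts. In the Hep3B line these were, for fibroblasts, LUM (ENSG00000139329, chr12:91102629-91111831), 0.638 ± 0.321 to 3.06 ± 0.0219 FPKM, and PDGFRA (ENSG00000134853, chr4:54229097-54298247), 0.459 ± 0.00461 to 2.63 ± 0.139 FPKM. For endothelium they were EGFL7 (ENSG00000172889, chr9:136658856-136672678), 114 ± 6.97 to 10.4 ± 0.138 FPKM, and ESAM (ENSG00000149564, chr11:124752583-124762290), 3.95 ± 0.238 to 0.58 ± 0.00871 FPKM. Macrophage genes were LYZ (ENSG00000090382, chr12:69348341-69354234), the lysozyme gene, 7.66 ± 0.285 to 40.9 ± 1.2 FPKM, and CD14 (ENSG00000170458, chr5:140631728-140633701), 9.19 ± 1.08 to 1.59 ± 0.0811 FPKM. Lymphocyte genes were CORO1A (ENSG00000102879, chr16:30182827-30189076), 9.08 ± 0.212 to 1.74 ± 0.0221 FPKM, and LCP1 (ENSG00000136167, chr13:46125920-46211871), 0.0431 ± 0.00192 to 0.17 ± 0.0267 FPKM. Neutrophil genes S100A9 (ENSG00000163220, chr1:153357854-153361027), 0.597 ± 0.0179 to 1.17 ± 1.48 FPKM, and S100A8 (ENSG00000143546, chr1:153390032-153391188), 0 ± 0 to 0.387 ± 0.547 FPKM, were low. Low too were the erythroid genes HBG2 (ENSG00000196565, chr11:5253190-5645789), 0 ± 0 to 0.0212 ± 0.00948 FPKM, and ALAS2 (ENSG00000158578, chrX:55009055-55031064), 0.0165 ± 0.0233 to 0.0201 ± 0.0090 FPKM, the muscle gene TNNI2 (ENSG00000130598, chr11:1838989-1841680), 0.065 ± 0.092 to 0.0917 ± 0.11 FPKM, and the adipocyte gene CIDEC (ENSG00000187288, chr3:9866711-9880254), 0.657 ± 0.104 to 0.145 ± 0.0754 FPKM. Lung genes FOXJ1 (ENSG00000129654, chr17:76136333-76141299), 289 ± 18.4 to 17.3 ± 1.2 FPKM, and ABCA3 (ENSG00000167972, chr16:2275881-2340746), 11.96 ± 0.838 to 1.65 ± 0.000976 FPKM, stood higher in the parental cells. The same was true of creatine kinase CKM (ENSG00000104879, chr19:45306414-45322977), 27.9 ± 1.27 to 4.27 ± 0.265 FPKM, and CFD (ENSG00000197766, chr19:859643-863630), 139 ± 13.2 to 10.4 ± 0.426 FPKM. Of these genes, LYZ, LUM and PDGFRA were called higher in the xenografts, LYZ in all 3 forms too and LUM and PDGFRA not.

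In the SK-Hep1 line the fibroblast markers THY1 (ENSG00000154096, chr11:119417378-119424985), 19.6 ± 0.386 to 4.52 ± 0.162 FPKM, and ACTA2 (ENSG00000107796, chr10:88935074-88991339), 13.7 ± 0.394 to 4.45 ± 0.286 FPKM, and the endothelial gene ROBO4 (ENSG00000154133, chr11:124883691-124898500), 8.96 ± 0.521 to 2.07 ± 0.00905 FPKM, fell in all forms. EGFL7 went from 151 ± 5.92 to 21.9 ± 1.08, CD14 from 12.5 ± 0.0911 to 4.55 ± 0.555, FOXJ1 from 38.4 ± 1.42 to 8.07 ± 0.144, ABCA3 from 19.1 ± 0.355 to 6.31 ± 0.173 and CFD from 82.5 ± 0.157 to 15.7 ± 1.22 FPKM. The other markers named for this line were below 1 FPKM. Blood cell genes were FCER1G (ENSG00000158869, chr1:161215234-161220699), 0 ± 0 to 0.0613 ± 0.00506 FPKM, CORO1A, 0.841 ± 0.221 to 0.158 ± 0.0112 FPKM, and CD79A (ENSG00000105369, chr19:41877120-41881372), 0.634 ± 0.178 to 0.0717 ± 0.00332 FPKM. Neutrophil genes were LTF (ENSG00000012223, chr3:46435645-46485234), 0.381 ± 0.0077 to 0.0761 ± 0.00352 FPKM, and ELANE (ENSG00000197561, chr19:851014-856247), 0.171 ± 0.045 to 0.0338 ± 0.00954 FPKM. Erythroid HBD (ENSG00000223609, chr11:5232678-5235370) and HBG2 were at 0.233 ± 0.0516 to 0.00981 ± 0.0139 and 0.0171 ± 0.0242 to 0.00514 ± 0.00727 FPKM. Muscle CKM and MYH2 (ENSG00000125414, chr17:10521148-10549957) were at 0.0425 ± 0.000858 to 0.0839 ± 0.0237 and 0 ± 0 to 0.0346 ± 0.00447 FPKM, and adipocyte PLIN1 (ENSG00000166819, chr15:89664365-89679427) at 0.065 ± 0.0144 to 0.0503 ± 0.00133 FPKM. Mouse cells were not assessed.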
